A study of Mus musculus with 10 samples.

How the data were processed

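Total RNA was measured by sequencing on an Illumina HiSeq2000 in 10 libraries of mouse embryonic fibroblasts (MEFs), which are primary connective tissue cells grown out of embryos. Per the labels, the cells came from C57BL/6 mice in which the H3f3b locus, a gene for the histone variant H3.3, had been exchanged for a tagged H3.3-HA cDNA. The labels name a naive and a pretreated arm, each sampled at 0, 1, 2, 4 and 6 h, with 1 library per arm and time. Interferon-beta (IFN-β), a secreted antiviral cytokine, is stated at 100 U per ml for the whole series. The dose, length and washout of the pretreatment are not given in the sources used here, and the hours were read as time after IFN-β was added.

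The submitters' processing notes name Bowtie, TopHat, Cufflinks 1.2.1 and the genome build mm10, with no order or role. One table was used. Per the file headers it holds, for each RefSeq transcript of mm10, a tag count and an RPKM value per library. The counts were deposited unnormalised. The RPKM values (reads per kilobase of transcript, scaled to sequencing depth) were computed by the authors before deposit. In 10637 transcripts above 5 RPKM in every library, the ratio of count to RPKM deviated from a constant per library and transcript by at most 0.000254 on the log2 scale. The deposited RPKM is thus a count rescaled by 1 factor per library and 1 per transcript, and how the library factor was set is not given in the sources used here. The counting tool, the use of strand and the treatment of reads that align to several places are not given in the sources used here. Reads of overlapping genes and of near-identical genes cannot be separated, which concerns H2-Q6 and H2-Q8, H2-Q7 and H2-Q9, H2-D1 and H2-L, Oas1a and Oas1g, Ifit3 and I830012O16Rik, Pydc3 and Pydc4, Mir675 inside H19, and the histone genes.

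The table had 30646 transcripts, of which 15 named no gene. These held between 0.0158% and 0.0193% of the counts of a library and were left out of library sizes and tests. The other transcripts carried 23370 gene symbols. For 4306 symbols with more than 1 transcript, the transcript with the highest mean RPKM was kept. Of the kept symbols, 353 had a transcript listed at several loci, and their coordinates are not used. Genes with at least 1 RPKM in at least 2 of the 10 libraries were tested, which left 12168 genes.

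The design had been fixed for RPKM values, with limma on log2(RPKM + 1). Because the table also held counts, the tests were made on the counts with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, trimmed mean of M values scaling), and limma became an added alternative. The groups have no replicates, so the time points took their place. The arms were compared in a model with time point and arm, which left 4 residual degrees of freedom. The mean of 2, 4 and 6 h was compared with 0 h in the same model, as was 1 h with 0 h. A term for arm by stimulation (0 h against all later times) was added to test a difference in induction, which left 3 residual degrees of freedom. The p-values therefore measure how far differences vary between time points and arms, not between cultures. They were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors (SE) were taken as the log2 fold change divided by the root of the F statistic. Comparisons of single libraries were made on log2(RPKM + 1), without p-values, and a gene was counted as apart at a fold of 2 or more. The pseudocount makes the fold of genes of low RPKM too small.

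The 31 gene lists were written from general knowledge before the data were examined, as were the tests, the filter, the rule for named genes and the alternatives other than those said to be added. Lists were tested with camera (limma) with its preset correlation of 0.01 and with an estimated correlation. They were also tested with fry (limma), which tests a list's own members without setting them against other genes. In single-library comparisons the median of a list was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Named genes were the 10 with the largest positive and the 10 with the largest negative log2 difference among the genes called in each test. To these came the 15 largest rises and 5 largest falls of the naive course at 6 h that also went the same way at 2 and 4 h. For pretreated against naive at 0, 1, 2 and 6 h, the 10 largest rises and 5 largest falls were taken. The 29 genes of an interferon panel and the 4 most highly expressed members of each list completed the rule, and members of a list may be named beside it. Some genes that the rule takes are not reported here.

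The tests of the arms, of stimulation, of 1 h against 0 h and of the difference in induction were tested on simulated counts with the libraries' own depths, in which 200 of 12168 genes were changed. Between the arms, 44.8% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 3 of 155 calls were false. For stimulation against 0 h the shares were 19.4%, 71.6% and 98.5%, with 12 false of 138 calls. For the difference in induction they were 0%, 1.49% and 68.2%, with 7 false of 53 calls, so this test mainly found simulated changes of 4-fold, the largest simulated. For 1 h against 0 h they were 2.99%, 61.2% and 93.9%, with 11 false of 116 calls. The linear trend and the models with grouped times were not simulated. Each simulated change was the same at every time it covered. The shares therefore need not hold for interferon genes, whose arm difference changed with time, which counts as error.

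Alternatives covered the pseudocount, the filter, scaling by median ratio, quantile normalisation, the trend in limma, transcripts summed per symbol, each time point left out, models without a term for time or arm, other groupings of the times, and the correlation in camera. Both libraries of 0 h were left out only in the test of the arms. DESeq2, limma, models with separate arm differences for 0 h, for 1 and 2 h and for 4 and 6 h, and fits without some pretreated libraries were added after the data had been seen. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.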

Results

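Transcript abundance was measured in MEFs that met IFN-β for the first time (naive arm) and in MEFs that had been exposed to interferon beforehand (pretreated arm), at 0, 1, 2, 4 and 6 h. The design asks how an earlier interferon exposure alters the state of the cells before stimulation and the response that follows it. Each arm and time had 1 library, so no value below has a replicate of its own group. No library is labelled as unstimulated at 1 to 6 h. Changes from 0 h therefore cannot be told apart from effects of time in culture or handling. Depth was high and uneven. The naive libraries held 94.4, 151, 109, 254 and 261 M counts (M, mega) over the kept transcripts from 0 to 6 h, and the pretreated libraries 129, 146, 83.9, 241 and 269 M. In each arm the 4 and 6 h libraries were thus the deepest. Between 11607 and 11815 genes reached 1 RPKM in a library. The ribosomal precursor transcript Rn45s took 3.90% of the counts in the pretreated 0 h library and 2.85% in the pretreated 1 h library, against 0.974% to 1.51% in the other 8.

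Before stimulation, the pretreated cells already carried high levels of interferon-induced transcripts. Ifit3, an antiviral RNA-binding protein gene, stood at 1.38 RPKM in the naive and 167 RPKM in the pretreated 0 h library. Oasl2, of the oligoadenylate synthetase family, stood at 1.27 and 165 RPKM, and Irf7, a transcription factor of interferon induction, at 2.22 and 180 RPKM. Isg15, which encodes a ubiquitin-like modifier, stood at 0.608 and 82.7 RPKM. B2m, the light chain of MHC class I molecules, was already at 990 RPKM in naive cells and was at 6861 RPKM in pretreated cells.

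Of the 12168 genes, 311 were 2-fold or more higher in the pretreated 0 h library and 102 were 2-fold or more lower. Among antiviral effectors 29 of 32 were 2-fold higher and 0 were 2-fold lower, with a median log2 difference of 2.76. In the list of MHC class I and antigen processing genes, 18 of 20 were 2-fold higher (median 2.75), among them H2-K1 with 9.94 RPKM in naive and 325 RPKM in pretreated cells. The interferon-inducible GTPases, which act on vacuoles of intracellular pathogens, had 15 of 18 members 2-fold higher (median 3.27), the ISG15 and ubiquitin-type ligases 14 of 15 (median 2.15) and the nucleic acid sensors 9 of 16 (median 1.86). Medians of these 5 lists lay at the 100th percentile of random lists matched on expression. Chemokines and cytokines were less far apart, with 3 of 16 members 2-fold higher and a median of 0.28. Cxcl10, a chemokine that attracts T cells, stood at 0.631 and 11.7 RPKM.

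The genes lowest in the pretreated 0 h library included the imprinted noncoding RNA H19, with 110 RPKM in naive and 9.39 RPKM in pretreated cells. Igfbp2, a binding protein for insulin-like growth factors, had 45.6 and 5.34 RPKM, and Fmod, a collagen-binding proteoglycan, 27.9 and 5.03 RPKM. Within the pretreated arm these genes did not hold a steady level. H19 was at 43.8 and 44.4 RPKM in the pretreated 1 h and 4 h libraries, and between 9.19 and 9.78 RPKM in the other 3. Fibroblast matrix genes had a median log2 difference of -0.53 and cell cycle genes of -0.31, both at the 0th percentile of random lists, with 2 of 21 and 0 of 24 members 2-fold lower. The noncoding RNA Rmrp, a component of a nuclear ribonuclease, stood at 5.98 RPKM in the naive and 76.0 RPKM in the pretreated 0 h library, and the replication-dependent histone genes had a median log2 difference of 0.81. Of the marker lists for other cell types, each with 2 to 5 members past the filter, 0 members were 2-fold apart at 0 h.

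**Figure D1:**
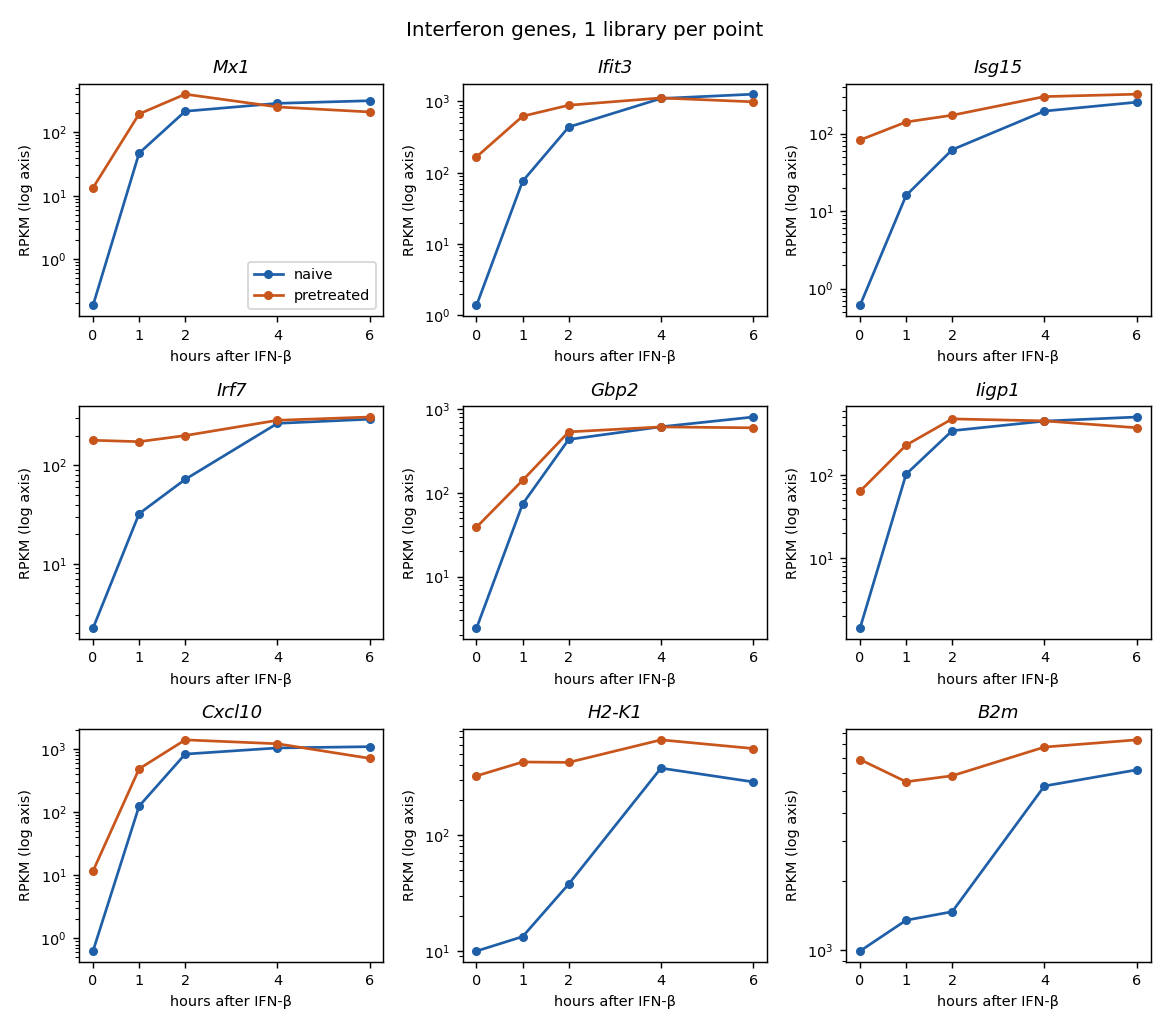
RPKM (log axis) of 9 interferon genes against hours after IFN-β, with 1 library per point, naive in blue and pretreated in orange. Isg15 started at 0.608 RPKM in naive and 82.7 RPKM in pretreated cells and reached 254 and 322 RPKM at 6 h.

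In naive cells, IFN-β was followed within 1 h by high levels of a group of antiviral and chemokine transcripts, and the number of genes apart from 0 h grew with time. Cxcl10 went from 0.631 RPKM at 0 h to 126 RPKM at 1 h, 840 RPKM at 2 h and 1101 RPKM at 6 h, a log2 difference of 9.40 at 6 h. Ifit3 reached 76.0 RPKM at 1 h and 1262 RPKM at 6 h, and Mx1, a dynamin-like antiviral GTPase gene, 47.0 and 315 RPKM from 0.186 RPKM at 0 h. The guanylate-binding protein gene Gbp2 went from 2.41 to 73.7 RPKM at 1 h and 810 RPKM at 6 h. At 1 h 6 of 20 MHC class I genes were 2-fold or more above naive 0 h, against 21 of 32 antiviral effectors, and at 4 h 20 and 32 were. H2-K1 was at 9.94 RPKM at 0 h, 13.3 RPKM at 1 h, 37.7 RPKM at 2 h and 379 RPKM at 4 h.

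A fold of 2 or more above naive 0 h was seen in 246 genes at 1 h, 481 at 2 h, 695 at 4 h and 755 at 6 h. At these times 22, 154, 388 and 450 genes were 2-fold or more below it. At 6 h the median log2 difference was 6.23 over the 29 genes of the interferon panel, 5.77 over the GTPases, 4.85 over the antiviral effectors, 4.11 over the sensors, 4.04 over the ISG15 and ubiquitin-type ligases, 3.45 over the PARP family and 3.26 over the MHC class I genes. At 1 h the panel was at 3.26 and the GTPases at 2.89. Some regulators were at their highest early. Irf1, an interferon-responsive transcription factor, was at 18.6 RPKM at 0 h, 205 RPKM at 1 h and 87.4 RPKM at 6 h. Socs1, a feedback inhibitor of cytokine receptor signalling, was at 8.91, 161 and 65.0 RPKM. Among the genes furthest below naive 0 h at 6 h, the small nucleolar RNA host gene Snhg9 went from 30.8 to 4.40 RPKM, the deiodinase gene Dio3 from 24.4 to 3.31 RPKM and the linker histone gene H1fx from 70.1 to 16.9 RPKM. Of the cell cycle genes, 15 of 24 were 2-fold or more below naive 0 h at 4 h and 10 at 6 h. At 6 h 2 of 4 neural markers were also 2-fold or more below it (median -1.06). At least 2-fold above it were 1 of 3 macrophage markers, 1 of 2 epithelial markers and 2 of 9 nuclear and small noncoding RNAs.

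Over both arms, interferon genes were among the largest rises at 2 to 6 h over 0 h, and most cell cycle genes fell. Cxcl10 rose by 8.04 on the log2 scale (SE 1.24, edgeR adjusted p = 0.00577), Gbp5 by 7.32 (SE 0.82, edgeR adjusted p = 0.00498) and Ifit2 by 6.40 (SE 0.94, edgeR adjusted p = 0.00552). Rsad2, the antiviral enzyme viperin, rose by 6.68 (SE 1.58, edgeR adjusted p = 0.0167). Daxx, a chaperone that deposits H3.3, rose by 2.52 (SE 0.31, edgeR adjusted p = 0.00498). Ccna2, the gene for cyclin A2, had a log2 change of -0.68 (SE 0.12, edgeR adjusted p = 0.00787).

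In edgeR, 4859 of 12168 genes passed, 2421 higher and 2438 lower, of which 657 and 175 changed 2-fold or more. Of the GTPases 17 of 18 rose (18 adjusted over the list alone). Of the antiviral effectors 21 of 32 rose (22 adjusted over the list alone), of the ISG15 and ubiquitin-type ligases 14 of 15 (15), of the MHC class I genes 13 of 20 (17), of the sensors 12 of 16 with 1 lower (14 and 1), and of the panel 16 of 29 (18). Of the PARP family 9 of 10 rose, among them Parp14 by 3.73 (SE 0.92, edgeR adjusted p = 0.0193), and Parp1 fell. Of the chemokines and cytokines 10 of 16 rose and of the cell death and PML body genes 9 of 16. Of the interferon signalling factors 6 of 13 rose, and Irf3 fell. Socs1 was among 4 of 11 feedback regulators that rose, with a log2 change of 3.03 (SE 0.41, edgeR adjusted p = 0.00526), and 1 fell.

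Several genes with large folds in the naive course did not pass in this model, in which an arm difference that changes with time counts as error. Ifit3 had an edgeR adjusted p of 0.0594, Isg15 of 0.0796, Irf7 of 0.178, and B2m of 0.143. With camera's preset correlation 13 of the 31 lists were called, and 0 with an estimated correlation, where the adjusted p was 0.555 for most interferon lists, 0.609 for the MHC class I genes and 0.167 for the chemokines. The fry adjusted p was 0.00294 for the chemokines and cytokines, 0.0306 for the GTPases, sensors and cell cycle genes and 0.0387 for the antiviral effectors. For the MHC class I genes the fry adjusted p was 0.0708.

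Of the 24 cell cycle genes 18 fell and 2 rose. The mitotic genes Cdc20 and Aurka fell by 1.51 (SE 0.15) and 1.26 (SE 0.15) on the log2 scale, and the replication licensing gene Mcm6 rose by 0.87 (SE 0.16). In the list of H3.3 genes and histone chaperones 5 of 13 rose and 5 fell. H3f3a rose by 0.27 (SE 0.08), and Asf1a by 1.07 (SE 0.19). Asf1b and Chaf1a, of chaperones that act at replication, fell by 0.92 (SE 0.16) and 0.90 (SE 0.16). The H3f3b transcript, whose locus had been exchanged for the tagged cDNA in these cells, stayed between 10.6 and 14.9 RPKM in all 10 libraries. Its value may therefore not measure an unaltered H3f3b gene. Of the H3K36 methyltransferases and elongation factors 3 of 14 rose and 3 fell. The NF-kB targets had 5 of 15 members higher and 1 lower, the p53 targets 1 of 16 higher and 6 lower, and the immediate early genes 3 of 23 higher and 3 lower. Of the fibroblast matrix genes 2 of 21 rose and 3 fell, and of the contractile genes 0 of 10 passed. Counts for the remaining cell function lists were 1 of 21 higher for cholesterol synthesis, 2 of 15 higher and 1 lower for the unfolded protein response, and 4 of 18 in each direction for oxidative phosphorylation. Of the ribosomal protein genes 3 of 22 fell, and of the reference genes 1 of 14 rose and 4 fell.

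Of the replication-dependent histones 5 of 12 fell and 1 rose, and of the nuclear and small noncoding RNAs 2 of 9 rose and 2 fell. The strongest fall was that of Rmrp, with a log2 change of -2.74 (SE 0.67, edgeR adjusted p = 0.0191). In the pretreated 0 h library Rmrp stood at 76.0 RPKM against 5.98 RPKM in naive cells. In the naive arm 0 of the 9 were 2-fold or more below 0 h at 2, 4 or 6 h. The fall of Rmrp thus rests on the pretreated arm and its single 0 h library. Of the markers of other cell types, 0 of 3 for macrophages, 0 of 2 for epithelium and 0 of 4 for muscle passed, 1 of 5 for endothelium rose and 1 fell, and 1 of 4 for neural cells rose and 2 fell. Without the pretreated 0 h library, which leaves 1 library at 0 h, the count of genes past the threshold was 2075 (1195 higher, 880 lower). With quantile normalisation in limma 2023 genes were higher and 3115 lower, a share of 39.4% higher against 49.8% in edgeR.

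At 1 h the count of genes past the edgeR threshold against 0 h over both arms was 0, with 1383 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.164. No other tool was run on this contrast. Adjusted over the list alone, 6 of 16 chemokines and cytokines, 4 of 11 feedback regulators, 3 of 15 NF-kB targets and 3 of 29 panel genes were higher at 1 h, with camera adjusted p of 0.0560, 0.0976, 0.500 and 0.500 with an estimated correlation. The fry adjusted p of these lists was 0.01715, 0.01715, 0.2335 and 0.2335. Adjusted over the list alone, 2 of 9 nuclear and small noncoding RNAs were higher. Of 12 replication-dependent histones 1 was higher and 1 lower.

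**Figure D2:**
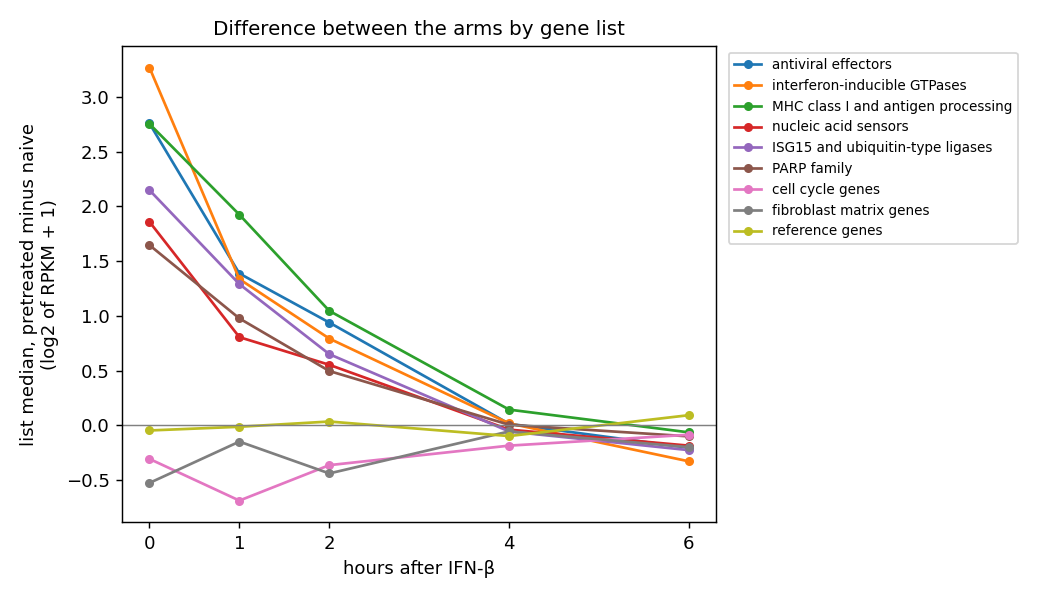
Median log2 difference (RPKM + 1) between the pretreated and the naive library at each time, for 9 gene lists, against hours after IFN-β. The antiviral effectors start at 2.76, reach 0.01 at 4 h and lie at -0.20 at 6 h, while the reference genes stay between -0.10 and 0.09.

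At matched times after stimulation, interferon transcripts were higher in pretreated than in naive cells at 1 and 2 h, and close to or below the naive level in most lists at 4 and 6 h. At 1 h H2-K1 stood at 13.3 RPKM in naive and 428 RPKM in pretreated cells, Ifit3 at 76.0 and 620 RPKM, Rsad2 at 21.5 and 305 RPKM, and Mx1 at 47.0 and 195 RPKM. At 4 h Ifit3 was at 1099 and 1118 RPKM and Mx1 at 287 and 252 RPKM. At 6 h Mx1 was at 315 and 210 RPKM and Cxcl10 at 1101 and 719 RPKM, so that the pretreated library was the lower one.

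The number of genes 2-fold or more higher in the pretreated library was 188 at 1 h, 189 at 2 h, 29 at 4 h and 19 at 6 h, and the number 2-fold or more lower was 99, 116, 16 and 26. Over the panel the median log2 difference was 3.48 at 0 h, 1.72 at 1 h, 0.76 at 2 h, 0.04 at 4 h and -0.23 at 6 h. Over the GTPases it was 3.27, 1.34, 0.79, 0.02 and -0.33, and over the MHC class I genes 2.75, 1.92, 1.05, 0.14 and -0.06. At 6 h the medians of the panel, the GTPases, the antiviral effectors, the sensors and the ISG15 and ubiquitin-type ligases lay at the 0th percentile of matched random lists. At 6 h 2 of 20 MHC class I genes were 2-fold or more higher, H2-Q6 with 15.2 RPKM in naive and 42.1 RPKM in pretreated cells and H2-Q7 with 9.27 and 24.1 RPKM, both uncertain because near-identical genes share their reads. Chemokines and cytokines had medians of 0.39, 0.53, 0.30 and 0.22 from 1 to 6 h. The interferon signalling factors had a median of -0.01 at 1 h.

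Some genes were much lower in the pretreated library at 1 h. Socs3, a feedback inhibitor of signalling by cytokines of the interleukin-6 family, was at 213 RPKM in naive and 15.9 RPKM in pretreated cells. The NF-kB cofactor gene Bcl3 was at 94.4 and 10.7 RPKM, and the transcription factor gene Cebpd at 110 and 16.2 RPKM. The hyaluronan synthase gene Has1 was at 12.9 and 1.96 RPKM. At 0 h these 4 genes had differed between the arms by at most 0.24 on the log2 scale. The immediate early genes had a median log2 difference of -0.46 at 1 h, with 5 of 23 members 2-fold or more lower, and of 0.46 at 4 h.

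The fold over an arm's own 0 h was smaller in the pretreated arm, whose starting level was higher. At 6 h the median log2 change of the panel was 6.23 in naive and 1.51 in pretreated cells, that of the antiviral effectors 4.85 and 1.77, and that of the GTPases 5.77 and 2.54. For the test of this difference, arm by stimulation in edgeR, the count of genes past the threshold was 0, with 741 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0516. DESeq2 called 133 genes and limma 15. Adjusted over the list alone, the change after stimulation was smaller in the pretreated arm for 16 of 18 GTPases, 19 of 32 antiviral effectors, 11 of 15 ISG15 and ubiquitin-type ligases, 9 of 16 sensors, 8 of 20 MHC class I genes and 21 of 29 panel genes. The median log2 difference of the change was -3.95 for the GTPases and -3.52 for the antiviral effectors. Signs of RNA quality went the same way, with 3 of 9 nuclear and small noncoding RNAs and 1 of 12 replication-dependent histones lower, adjusted over the list alone (camera adjusted p = 0.181 and 0.375 with an estimated correlation). With camera's preset correlation 19 of 31 lists were called, and 0 with an estimated correlation, where the adjusted p was 0.162 for most interferon lists, 0.200 for the PARP family and 0.267 for the MHC class I genes. The fry adjusted p was 0.185 for the GTPases and the panel and 0.196 for the antiviral effectors.

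**Figure D3:**
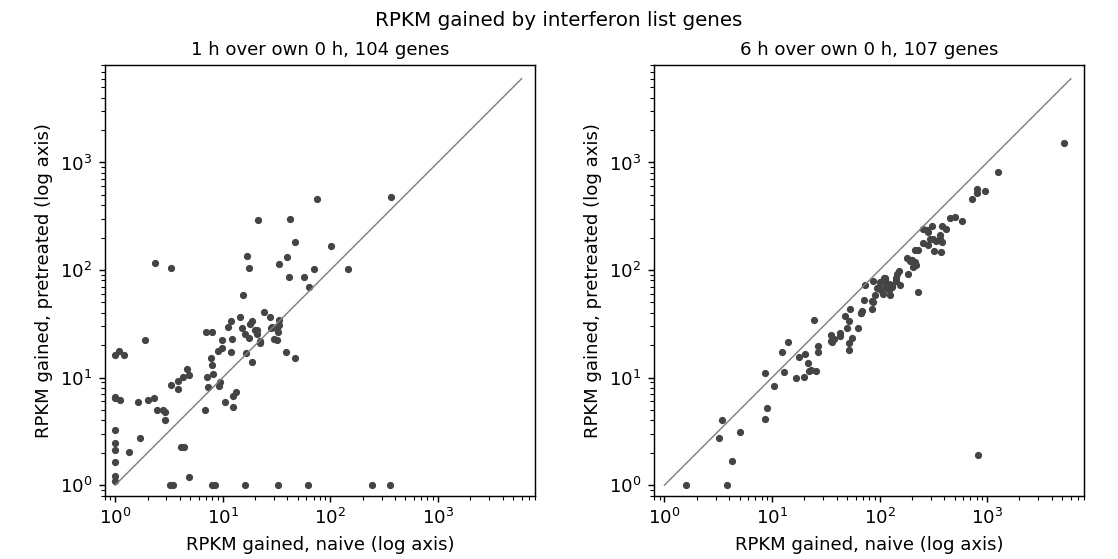
RPKM gained over the own 0 h library by genes of 6 interferon lists, naive on the horizontal and pretreated on the vertical axis (both log axes, gains under 1 RPKM drawn at 1), at 1 h (104 genes) and 6 h (107 genes), with the line of equal gain. At 1 h 74 genes gained more in pretreated cells, and at 6 h 5 did.

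Over the 5 times, Pcolce2, Prg4 and Serpina3n, which encode secreted proteins, were among the genes lower in pretreated cells, and the prostaglandin synthase gene Ptgs2 and the histone gene Hist1h4h among those higher. Pcolce2, an enhancer of procollagen processing, had a log2 difference of -1.68 (SE 0.07, edgeR adjusted p = 0.000435) and was lower in pretreated cells at 5 of 5 times. The joint lubricant gene Prg4 had one of -1.52 (SE 0.08, edgeR adjusted p = 0.00165) and the protease inhibitor gene Serpina3n one of -3.00 (SE 0.42, edgeR adjusted p = 0.0331). Serpina3n was at 3.14 RPKM in naive and 1.65 RPKM in pretreated cells at 0 h, and at 11.5 and 0.958 RPKM at 4 h. Ptgs2 had a log2 difference of 1.10 (SE 0.08, edgeR adjusted p = 0.00594), with 15.3 RPKM in naive and 27.9 RPKM in pretreated cells at 0 h and 27.4 and 70.1 RPKM at 4 h. Hist1h4h had one of 1.32 (SE 0.14, edgeR adjusted p = 0.0171). Saa3, an acute-phase gene, also passed, but was listed at 0 in the naive 0 h and 2 h libraries and was at 0.609 and 1.27 RPKM in the pretreated 1 h and 6 h libraries.

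In edgeR 154 genes passed, 47 higher and 107 lower in pretreated cells, of which 7 and 19 differed 2-fold or more. Of the cell cycle genes 3 of 24 were lower (16 adjusted over the list alone), namely Mki67, Ccnb1 and Ccnb2. Of the fibroblast matrix genes 3 of 21 were lower (12 adjusted over the list alone), namely Fn1, Fbn1 and Timp1. The median log2 difference of the matrix list was -0.53, -0.44 and -0.20 at 0, 2 and 6 h, and -0.15 and -0.05 at 1 and 4 h, the times of the pretreated libraries in which H19 was high. Of the markers of other cell types, 1 of 2 for epithelium was higher, Krt19 by 1.14 (SE 0.15, edgeR adjusted p = 0.0285), at 1.08 RPKM in the pretreated and 0.451 RPKM in the naive 0 h library. The counts for macrophage, endothelial, muscle and neural markers were 0 of 3, 0 of 5, 0 of 4 and 0 of 4. Adjusted over the list alone, 1 of the 3 macrophage markers was higher. Of the chemokines and cytokines 1 of 16 was higher (4 adjusted over the list alone). The replication-dependent histones had 2 of 12 members higher (6 adjusted over the list alone), Hist1h1c and Hist1h2bc. In the antiviral, GTPase, sensor, ISG15 and panel lists 0 members passed, and in the MHC class I list 0 (5 adjusted over the list alone). In this model an arm difference that changes with time counts as error. With camera's preset correlation 14 of 31 lists were called, and 0 with an estimated correlation, where the adjusted p was 0.596 for the cell cycle, matrix, histone and MHC class I lists, 0.613 for the antiviral, GTPase and panel lists and 0.637 for the sensors. The fry adjusted p was 0.0987 for the cell cycle, matrix and histone lists and 0.320 for the antiviral and GTPase lists.

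The count of 154 depended on the times used. Leaving out both libraries of 0, 1, 2, 4 or 6 h gave 7, 2, 2, 156 and 7 genes, leaving out only the pretreated 0 h library gave 7, and leaving out the pretreated 1 h and 4 h libraries gave 14. In edgeR with separate arm differences for groups of times, a model chosen after the data had been seen, 707 genes differed between the arms at 1 and 2 h, 422 higher and 285 lower in pretreated cells, and 92 of them were among the 154. Those higher included 19 of 32 antiviral effectors (26 adjusted over the list alone), 14 of 20 MHC class I genes (19), 7 of 18 GTPases (17) and 12 of 29 panel genes (23). H2-K1 was higher by 4.25 (SE 0.37, edgeR adjusted p = 0.0116) and Oas2 by 4.19 (SE 0.52, edgeR adjusted p = 0.0202). Those lower included 10 of 24 cell cycle genes (16 adjusted over the list alone), among them Top2a by -0.73 (SE 0.11, edgeR adjusted p = 0.0278), and Bcl3 by -2.52 (SE 0.32, edgeR adjusted p = 0.0207). Socs3 had an edgeR adjusted p of 0.0557. Of the markers of other cell types, Krt19 (1.17, SE 0.21, edgeR adjusted p = 0.0421) and the macrophage marker Ctss (4.10, SE 0.56, edgeR adjusted p = 0.0252) were higher, and Ctss was listed at 0 in the naive 0 h and 1 h libraries. Of the replication-dependent histones 2 of 12 were higher, Hist1h1c by 0.71 (SE 0.12, edgeR adjusted p = 0.0345) and Hist1h2bc by 1.05 (SE 0.09, edgeR adjusted p = 0.0116), with a median of 0.64 over the list. At 4 and 6 h 2 genes differed, Serpina3n and Pcolce2, both lower in pretreated cells, and in every list the count over all genes tested was 0. The low count does not mean that all other differences were lost. Ptgs2 was higher by 1.08 (SE 0.11, edgeR adjusted p = 0.0149) at 1 and 2 h. At 4 and 6 h it was higher by 1.24 (SE 0.11, edgeR adjusted p = 0.156). Prg4 had differences of -1.64 and -1.42. Other differences did shrink, such as that of H2-K1, to 0.84 (SE 0.32). Adjusted over the list alone, 6 of 23 immediate early genes, 4 of 20 MHC class I genes and 4 of 16 p53 targets were higher at 4 and 6 h. Of 16 chemokines and cytokines 2 were higher and 2 lower, and 1 of 12 replication-dependent histones was higher. Of 2 epithelial markers 1 was higher and 1 lower, and 1 of 5 endothelial markers was lower. Of the immediate early genes, 4 (Egr1, Egr2, Egr3 and Nr4a1) were higher in the pretreated 1 h and 4 h libraries than in the other 3 of that arm, with Nr4a1 at 76.8 RPKM at 4 h and 5.93 RPKM at 2 h. The spread between 2 neighbouring times is the only error in this model.

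On mm10, Cxcl10 lies on chromosome 5 at 92346639 to 92348889 with 4 exons, Ifit3 on chromosome 19 at 34583529 to 34588982, Mx1 on chromosome 16 at 97447035 to 97462906 and Isg15 on chromosome 4 at 156199424 to 156200818. H2-K1 lies on chromosome 17 at 33996012 to 34000333, B2m on chromosome 2 at 122147687 to 122153082, Ptgs2 on chromosome 1 at 150100124 to 150108012 and Pcolce2 on chromosome 9 at 95637628 to 95695551. H19 lies on chromosome 7 at 142575532 to 142578146 and Socs3 on chromosome 11 at 117966087 to 117969366.

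**Figure D4:**
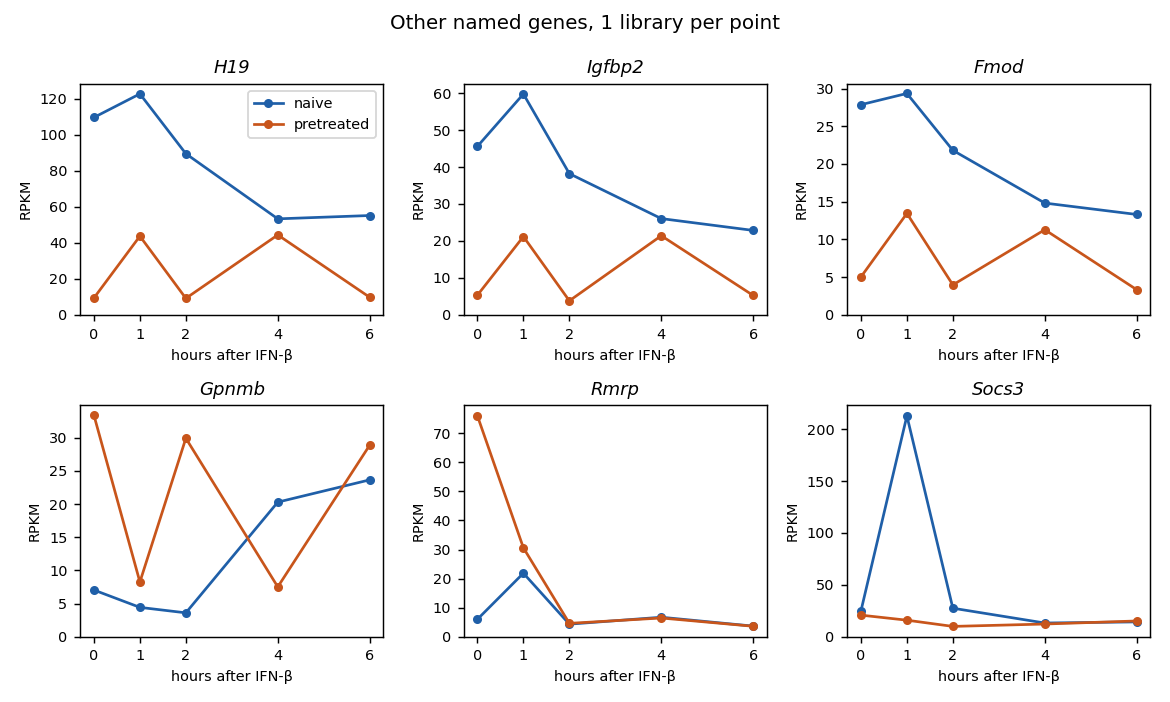
RPKM of 6 genes against hours after IFN-β, with 1 library per point, naive in blue and pretreated in orange. H19 alternates between about 9.39 and 44.4 RPKM in the pretreated arm, Rmrp is at 76.0 RPKM in the pretreated 0 h library, and Socs3 is at 213 RPKM in the naive 1 h library.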

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

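Of the tests of a changing arm difference, the linear trend was planned, and the comparison of 4 and 6 h with 1 and 2 h was chosen after the data had been seen. In edgeR the arm difference had a linear slope over hours in 76 genes, with a falling slope in 75 and a rising one in 1, Dio3. A slope does not show a steady course. The log2 difference of Gbp4 was 1.12, 2.33, 2.63, 0.94 and 0.54 at 0, 1, 2, 4 and 6 h. That of Oas2 was 5.11, 4.65, 3.01, 0.30 and 0.23. The smallest adjusted p was 0.0468. Of the 76 genes, 26 belonged to the interferon lists. These were taken here with the panel, the signalling factors, the chemokines and cytokines and the cell death and PML body genes, and held 159 members. Among them were Oas2, whose arm difference changed by -1.14 per hour on the log2 scale (SE 0.16), H2-K1 by -0.82 (SE 0.12) and Ifit2 by -0.59 (SE 0.06). In edgeR the arm difference at 4 and 6 h differed from that at 1 and 2 h in 20 genes, 17 lower and 3 higher at the later times. Singled out after their values were seen, the 3 were Cxcl1, by 2.72 (SE 0.23), Adora2b, by 1.75 (SE 0.17), and Fosl2, by 1.57 (SE 0.15). Of the 20 genes, 2 belonged to these lists, Cxcl1, a chemokine gene also listed as an NF-kB target, and Oasl1, the latter among the 17, with -2.01 (SE 0.17). Adjusted over the list alone, the difference was lower at the later times for 30 of 32 antiviral effectors and 17 of 18 GTPases. It was also lower for 19 of 20 MHC class I genes and 24 of 29 panel genes. Of 15 NF-kB targets 7 were higher and 1 lower.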

How the results depend on the processing

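Fits by DESeq2 and by limma as first designed, separate arm differences for groups of times, and fits without single pretreated libraries were chosen after the data had been seen. Of 103 comparisons of a main value with an alternative, 69 stayed within 1.5 times and 34 did not. For the arms (154 genes), no filter gave 316, a mean of 5 RPKM or more 87, quantile normalisation 250, no replicate block (no term for time) 9 and DESeq2 1371. Leaving out both libraries of a time gave between 2 and 156, the pretreated 0 h library left out 7, and the pretreated 1 h and 4 h libraries left out 14. Separate arm differences gave 707 at 1 and 2 h and 2 at 4 and 6 h. For stimulation against 0 h (4859 genes), the alternatives fixed beforehand, DESeq2 and limma stayed within 1.5 times, including 3662 without a replicate block for the arm, and only leaving out the pretreated 0 h library, which leaves 1 library at 0 h, moved further, to 2075. The difference in induction (0 genes) gave 23 in limma with a pseudocount of 0.1, 28 without a filter, 10 with a mean of 5 RPKM or more, 9 with quantile normalisation, 15 in limma with and without a trend, 133 in DESeq2, 76 as a linear trend and 20 as 4 and 6 h against 1 and 2 h. It stayed at 0 with median-ratio scaling, with summed transcripts and with 1, 2, 4 or 6 h left out in turn. This test cannot be fitted without 0 h. A pseudocount of 0.1 raised the counts of genes 2-fold apart from 413 to 720 for pretreated against naive at 0 h, from 268 to 485 and from 635 to 999 in the naive course at 1 and 2 h, and from 287 to 473, 305 to 589, 45 to 84 and 45 to 117 between the arms at 1, 2, 4 and 6 h, since it widens the folds of genes of low RPKM. A mean of 5 RPKM or more gave 198 at 2 h. With an estimated correlation in camera the lists called were 0 in place of 14 for the arms, 0 in place of 13 for stimulation and 0 in place of 19 for induction. The smallest fry adjusted p was 0.00294 for stimulation, 0.0987 for the arms and 0.185 for induction. Of 364 alternatives for the 20 named genes of the arm test 212 stayed past the threshold, 152 did not and 0 changed direction. Of 351 for the 20 of the stimulation test these counts were 322, 29 and 0. Median-ratio scaling shifted libraries by -0.05 to 0.06 on the log2 scale against the deposited RPKM. Against the scaling of the edgeR tests it moved them by at most 0.0134. Equal edgeR counts under it therefore say little about scaling. Other causes were not tested. Depth ran from 83.9 to 269 M counts, and its effect was not tested separately.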

Other observations

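All tests in this part were chosen after their results had been seen, with the bounds used to judge them, except the count over splits of the libraries and the test of a difference in induction, which were planned. Several genes of other groups stood apart in single libraries. At 1 h in naive cells the AP-1 gene Junb was at 159 RPKM and Ier3 at 70.4 RPKM, against 51.8 and 33.6 RPKM at 0 h, and at 1 h in pretreated cells they were at 40.5 and 14.4 RPKM. The contractile genes Tagln and Acta2 went from 311 and 1821 RPKM at naive 0 h to 97.6 and 883 RPKM at naive 6 h, and 5 of 10 contractile genes were 2-fold or more below naive 0 h there. At 0 h 2 of the 10 were already 2-fold lower in pretreated than in naive cells (median log2 difference -0.41). The median difference was -0.30 and 0.23 at 2 and 6 h, and 0.18 and 0.61 at 1 and 4 h, the times of the pretreated libraries that stood apart, and pretreated 6 h had 0 of 10 2-fold below its own 0 h. In the edgeR test of a difference in induction 0 of 10 passed, also when adjusted over the list alone, among 0 genes in all, 741 at an unadjusted p under 0.05, 133 in DESeq2 and 15 in limma. Cd274, the gene for the checkpoint ligand PD-L1, singled out after its values were seen, peaked at 2 h in both arms, at 40.4 RPKM in naive and 111 RPKM in pretreated cells, and was at 17.0 and 12.5 RPKM at 6 h. Of 16 macrophage markers 13 stayed below 1 RPKM in every library, with Cd14 highest at 8.29 RPKM. For endothelial markers the count was 7 of 12 (Egfl7 highest, 4.29 RPKM), for epithelial 10 of 12 (Cdh1, 5.07 RPKM), for muscle 8 of 12 (Acta1, 11.4 RPKM) and for neural markers 7 of 12 (Ncam1, 33.7 RPKM).

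The 154 genes called between the arms were set against other splits of the 10 libraries. Of 100 splits drawn from 126 possible ones, 2 called as many genes, the real one included, and the highest other split called 1373. With time in the model only the 16 splits that part both libraries of every time are comparable with the real one, which is too few for a share under 0.05, and the 11 others of these that were drawn called 0 genes. The split with 1373 genes has both 4 h libraries on one side and both 6 h libraries on the other. With time in the model it therefore measures the difference between the arms at 0, 1 and 2 h alone. At these times 413, 287 and 305 genes were 2-fold or more apart between the arms, against 45 at 4 h and 45 at 6 h. A wrong scaling of libraries would shift all genes alike, but 47 of the 154 were higher and 107 lower. Whichever common shift is taken, the 95% intervals of at least 78 of the 154 leave it out. At least 47 of these are built in, since the genes were called for differing from 0 and lie on both sides of it. The calls in both directions argue against scaling as the whole cause. An effect of the pretreatment and a difference between cultures or library batches of the arms stay open.

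At 1 h 74 of 104 interferon genes of 6 lists gained more RPKM in the pretreated than in the naive library. Transcripts carried over from the pretreatment on top of an equal gain would leave the gains alike, and their median log2 ratio was 0.68 (95% bootstrap interval 0.42 to 0.90), and 0.66 (0.42 to 0.89) after a rescaling that moved these libraries against each other by at most 0.00770. The 2438 genes that fell at 2 to 6 h had moved further at 1 h in the pretreated library, by a median of -0.14 on the log2 scale (-0.15 to -0.12), but these genes were chosen against the same 0 h libraries, which can build in part of that change. The intervals cover the spread between co-regulated genes only, and with 1 library per arm and time carry-over, scaling, a difference in timing or culture and a faster response after pretreatment cannot be told apart. The ratio of the gains was 0.28 (0.14 to 0.48) at 2 h, -0.40 at 4 h and -0.70 at 6 h.

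The pretreated 1 h and 4 h libraries stood apart from the pretreated 0, 2 and 6 h libraries in 65 genes (47 higher, 18 lower, 1.5-fold or more without overlap), against at most 15 genes for the other splits of that arm that do not follow time. The 65 held H19, Igfbp2, Fmod and Postn, 4 immediate early genes such as Egr1, and 0 members of the antiviral, GTPase, sensor or MHC class I lists. Genes that climb from 0 to 6 h can hardly meet this rule, so that 0 was nearly fixed in advance. It does not show that interferon genes escaped the split. Singled out after its values were seen, pretreated Ifi27l2a gained 115 and 180 RPKM at 1 and 4 h, but 7.36 and 98.3 RPKM at 2 and 6 h. Pretreated Isg15 instead gained 58.5, 89.9, 217.5 and 239.7 RPKM from 1 to 6 h. Among the 65, which side departed from the naive arm differed between genes. In the pretreated arm Postn was at 627 and 679 RPKM at 1 and 4 h, and at 285 to 326 RPKM otherwise. Its naive range was 470.8 to 572.5 RPKM. H19 was likewise nearer to its naive range, 53.4 to 123 RPKM, at 1 and 4 h. Hmga1 went the other way, at 145 and 148 RPKM at 1 and 4 h and 233 to 324 RPKM otherwise. Its naive range was 179 to 323.5 RPKM. An unlabelled culture or library batch is a candidate explanation, and no label gives one. Macrophages in some cultures are argued against by 6 of their abundant transcripts, at most 0.704 RPKM (Lyz2) in the 0, 2 and 6 h libraries, although Cd68 (3.12, 3.21 and 3.57 RPKM there, 1.89 and 1.94 RPKM at 1 and 4 h), and Gpnmb and Itgb2, singled out after their values were seen, followed the split. No biological explanation was tested, and without those 2 libraries the arm test called 14 genes in place of 154.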
